A study of Homo sapiens with 9 samples.

How the data were processed

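The samples were grown, treated and extracted as the labels describe: HEK293 Flp-In T-Rex cells of the b-39 subline received siRNA, cytoplasm was released with digitonin, poly(A)+ RNA was selected, and libraries were made with ScriptSeq v2. Samples were grouped by their labels into control, XRN1, SMG6/XRN1 and UPF1/XRN1, with 1 RNA-seq library in each. The libraries of RNA 5' ends and the CAGE library were not used here, so decapped and endocleaved fragments were not examined.

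The authors' processing is known only in part. Per the submitters' processing notes, reads were handled with CASAVA 1.8.2, Bowtie 0.12.7, TopHat2 2.0.6 and Cufflinks 2.0.2 and the genome was hg19, and those notes give the tools no role or order. The gene values are FPKM per assembled locus, made by the authors with Cufflinks as the deposited table's name says. The isoform values are a signal, estimated reads per assembled isoform scaled by 1 factor per library, which the authors deposited as spike-in normalised. The spike-in and the way its factor was computed are not given in the sources used here. The other deposited columns are the authors' identifiers, reference class codes and TRUE or FALSE marks per isoform. Tested on the file, the authors' NMD mark was TRUE exactly where both SMG6/XRN1 and UPF1/XRN1 were above 0 and over 2 times the control, with 0 mismatches. Of 28034 isoforms so marked, 12300 (43.9%) were listed at 0 in the control. Whether reads were counted by strand is not given in the sources used here, so overlapping and antisense genes and near-identical copies are uncertain.

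The gene table covers only part of the loci. It holds 22266, none listed at 0 in SMG6/XRN1 or UPF1/XRN1, while 1336 were listed at 0 in the control and 1294 in XRN1. Of the loci of the isoform table, 26292 are outside the gene table, among them that of GAPDH, which is therefore not in the gene comparisons. A value of 0 is treated as listed at 0, since it can be a failed estimate.

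Depth was read from the isoform signal, whose low values pile up on whole multiples of 1 step per library. The steps were 3.85, 4.05, 4.25 and 3.72 for control, XRN1, SMG6/XRN1 and UPF1/XRN1. Of loci with at most 20 reads, 85.8%, 84.5%, 86.0% and 86.6% came out whole within 0.01. Other loci hold fractions, because reads are shared among isoforms, so these are estimated reads and no count test was run on them. Read ratios carry exact conditional binomial intervals at 95%, scaled by the value of 1 read in each library as in the deposited spike-in normalisation, and shares carry exact Clopper-Pearson intervals at 95%. Intervals of reads cover counting error only. Intervals of shares of isoforms or loci treat these as independent draws and cover no error in their reads. A floor of 3 reads was used for a value under it.

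All sizes of change are log2((a + 1)/(b + 1)) of the deposited values, which understates the change of low genes. On the isoform signal, where 1 read was worth 3.72 to 4.25, the added 1 is less than 1 read. It hardly damps low isoforms, which can pass 2-fold on few reads. Genes needed a mean of at least 1 FPKM over the 4 libraries (12164 genes, 25 of them listed at 0 in some library). The isoform signal was not on the FPKM scale, so the fallback named in the design was used, a mean of at least the median of the nonzero means (30.9), which kept 61408 of 122816 isoforms, 11177 of them with a 0 in some library. A change was called at 2-fold. With 1 library per group no p-value was computed. The 3 main comparisons were XRN1 over control, SMG6/XRN1 over XRN1 and UPF1/XRN1 over XRN1, and 2 further ones set both co-depletions against the control.

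A total of 18 gene lists was fixed before the data were examined, with 458 entries. For each, the median log2 change was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. A list was called apart when its median fell at or outside the ends of their central 95%. The lists share members: 16 of the known NMD targets lie in another list, among them 4 splicing regulators, 4 ATF4 targets and 2 non-coding snoRNA hosts. The list of ATF4 targets shares 1 gene with the p53 targets, SESN2.

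The genes named in the text were also fixed beforehand. For each main comparison they were the 8 largest rises and 8 largest falls among genes with a symbol, a mean of at least 5 FPKM and no library listed at 0. For both co-depletions they were the 12 genes with the largest smaller rise, for isoforms the 5 largest rises in each co-depletion, and for each list up to 2 largest rises and 2 largest falls. XRN1, SMG6, UPF1 and HBB were always named. Some items that this rule picks are not reported here. Where at most 5 members of a list passed 2-fold, the others among them were named after their values were seen, as were the sums over gene families and the genes of the NMD share comparison. At 396 loci the symbol given covers under 80% of the reads of the locus, CUZD1 and the NPIP loci among them.

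Transcript types and structures came from GENCODE 29, an annotation of another genome build, matched by transcript identifier alone, so no coordinates are given. Of isoforms matching a reference transcript exactly, 92.9% were found there and 46.4% in the same version. For stop codons and untranslated regions, 88.8% of 25734 protein-coding isoforms had values, 17.3% in the same version. Isoforms were called changed without their gene where they rose 2-fold while the other isoforms, with at least 10 reads together, moved by under 1.5-fold. The expected overlap under a shared XRN1 library was drawn from 100 simulations of unchanged libraries. Their noise was normal and set from the robust spread of control against XRN1. That spread leaves out the tails, so the simulated overlap is no upper bound.

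Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5, centring on the median, and isoform signals summed per gene. A pseudocount of 50 for isoforms, their upper quartile as a filter, and summed signals with a pseudocount worth 1 FPKM (334 signal units) were added after the data were seen. Counts were taken as alike within 1.5 times, correlations within 0.1, the difference between class shares within 1.96 standard errors, lists by whether they stayed apart on the same side, and named genes by sign and by 2-fold. Loci were called discordant when the log2 changes of FPKM and of reads, the latter with the pseudocount worth 1 FPKM, differed by over 1. That pseudocount replaced a first version with 1, after its result was seen, and a test of whether such loci changed in amount was dropped because the choice of loci fixed its outcome.

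Scripts were tested on simulated data that held counting error only. For SMG6/XRN1 over XRN1 with 12149 genes, the 2-fold rule called 2% of genes changed 1.5-fold, 70% of those changed 2.5-fold, 96% at 4-fold, 94% at 8-fold and 0.159% of unchanged genes. Of 200 unchanged lists of 20 genes picked at random 4.5% were called apart, and 100% of lists shifted by 0.5 were. For 56930 isoforms the rule called 6%, 80%, 98% and 94% at those sizes. Intervals of read ratios covered the true value in 95.9% of 1000 draws. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.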

Results

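RNA sequencing of cytoplasmic poly(A)+ RNA was analysed from HEK293 Flp-In T-Rex cells, a human embryonic kidney line, of a subline labelled b-39. The cells had received a control siRNA, siRNA against XRN1, or siRNA against XRN1 together with siRNA against either SMG6 or UPF1. XRN1 is the main cytoplasmic exonuclease that degrades RNA from its 5' end. UPF1 is the RNA helicase at the centre of nonsense-mediated decay (NMD), the pathway that removes mRNAs on which translation stops early, and SMG6 is the endonuclease of that pathway. The series had 9 samples, of which the 4 RNA-seq libraries were used. The 4 libraries of RNA 5' ends and the 1 CAGE library, which the design text assigns to decay intermediates and cap sites, were not analysed here. Each condition had 1 RNA-seq library, so no difference had a replicate check, and every size of change describes these libraries.

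The gene table held FPKM values for 22266 loci and the isoform table held spike-in normalised signal for 199618 isoforms of 48558 loci. Low isoform signals lay on whole multiples of 1 step per library. That step gave 31476364 estimated reads for the control, 32970324 for the library labelled XRN1, 34649699 for SMG6/XRN1 and 35983000 for UPF1/XRN1. Ratios of reads are scaled by that step, which keeps the authors' spike-in normalisation. The intervals printed beside read ratios are 95% intervals and cover counting error only. After a filter on a mean of at least 1 FPKM, 12164 genes were compared.

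The targeted mRNAs were examined first. XRN1 stood at 7.80 FPKM in the control, 7.31 in the library labelled XRN1, 10.1 in SMG6/XRN1 and 6.50 in UPF1/XRN1. Its reads in the library labelled XRN1 were 0.894 of the control (95% interval 0.834 to 0.958). SMG6 stood at 4.77 FPKM in the control, 5.55 in XRN1 and 7.66 in the library labelled SMG6/XRN1. Its reads there were 1.30 times the control (1.16 to 1.45) and 0.982 times the library labelled XRN1 (0.883 to 1.09). UPF1 stood at 6.71 FPKM in the control, 11.6 in XRN1 and 8.59 in the library labelled UPF1/XRN1. Its reads there were 1.10 times the control (1.01 to 1.19) and 0.636 times the library labelled XRN1 (0.591 to 0.684). By FPKM, 2 of 5 targeted values lay below the control, so the targeted mRNAs did not check the labels, and each library is named here by its label. That count depends on the scale. Total spike-in normalised signal was lowest in the control, so ratios per sequenced read would be lower than the read ratios given here.

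HBB, the beta-globin gene widely used in nonsense reporters, stood at 139 FPKM in the control, 257 in the library labelled XRN1, 355 in SMG6/XRN1 and 747 in UPF1/XRN1. HBB rose by 1.53 on the log2 scale from the library labelled XRN1 to UPF1/XRN1. The steps from the control to XRN1 (0.88) and from XRN1 to SMG6/XRN1 (0.46) were under 2-fold.

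The library labelled XRN1 was compared with the control to see which RNAs change with the 5' exonuclease alone. Non-coding hosts of small nucleolar RNAs (snoRNAs), NMD factors, known NMD targets and targets of the stress-induced transcription factor ATF4 were higher as groups. Of the 12164 genes, 500 were at least 2-fold higher and 45 at least 2-fold lower. The log2 change of the median gene was 0.14, and after centring on it the counts were 362 higher and 65 lower. Directions rest on the label XRN1, which the XRN1 mRNA did not check.

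Among 16 measured non-coding snoRNA hosts of 22 listed, 8 rose, none fell, and the median log2 change was 1.02. SNHG15 rose by 1.79, from 12.4 to 45.5 FPKM, and SNHG12 by 1.77, from 37.2 to 129 FPKM. SNHG10 (-0.89) and DANCR (0.03) did not pass 2-fold. The series title names snoRNA host genes, so this list is not independent evidence of its direction. Of 54 measured protein-coding snoRNA hosts, 3 rose and the median was 0.27. The risers were the nucleolar protein gene NOP56 (1.43, from 391 to 1058 FPKM), TAF1D (1.11) and SNX5 (1.06). HSPA8, an abundant chaperone of the same list, had -0.66.

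Of 12 NMD factors, DHX34 (1.41) and the kinase SMG1 (1.21, from 5.40 to 13.8 FPKM) rose, none fell, and all 12 lay above 0. Of 25 known NMD targets, 6 rose, none fell, and all 25 lay above 0, with a median of 0.53. The kinase gene MAP3K14 rose by 1.26 from 0.653 FPKM, and the snoRNA host GAS5 rose from 176 to 412 FPKM. Of 24 ATF4 targets, 3 rose and none fell, with a median of 0.61. They were CHAC1 (1.35), NUPR1 (1.27) and asparagine synthetase ASNS (1.15, from 142 to 319 FPKM). The 53 ribosomal protein genes outside the list of snoRNA hosts had a median of 0.25, all lay above 0, and none passed 2-fold.

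Among 10000 random lists matched on expression, the medians of these 6 lists lay above the central 95%. The percentile was 100 for both the non-coding and the protein-coding snoRNA hosts, for the known NMD targets and for the ATF4 targets, 99.98 for the NMD factors and 99.99 for the ribosomal proteins. If list members varied independently, chance alone would give 0.9 of 18 lists apart in each comparison. Members that move together can put a list apart through any difference between 2 single libraries. The other 12 lists were not apart. Their percentiles were 94.6 for replication-dependent histones (median 0.33), with H4C15 up by 1.27, and 66.0 for interferon response genes (0.21). They were 58.4 for splicing regulators (0.09), with the kinase CLK4 (from 8.71 to 21.3 FPKM) and SRSF6 (1.04) up, and 56.4 for deadenylases and the exosome (0.12). They were 43.3 for the exon junction complex (0.07), 31.1 for decapping factors (0.08), 21.8 for p53 targets (0.07) with ZMAT3 down by -1.06, and 19.1 for the 2 measured mitochondrial mRNAs (-0.06). They were 16.1 for housekeeping genes (0.03), with GUSB up by 2.16, 4.98 for immediate-early mRNAs (0.03), 4.35 for markers of other cell types (-0.22) and 2.92 for nuclear-retained RNAs (-0.15), of which PVT1 rose by 1.75. Centring shifts every gene alike and leaves these percentiles as they are. With isoform signals summed per gene the exon junction complex median was -0.08, at percentile 2.37, which put that list apart below. The cell type markers had 3 measured members of 18, EPCAM (0.07), HBA1 (-0.22) and HBA2 (-0.33).

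The genes with the largest rises belonged mostly to repeated families. NPIP (3.80), NPIPP1 (3.60), NPIPL3 (from 5.78 to 61.5 FPKM), RP11-467M13.1 (3.27) and the polycystin pseudogene PKD1P1 at 2 loci (3.24 and 3.05) rose together. Summed, 4 NPIP loci went from 8.96 to 126 FPKM and 3 PKD1P loci from 7.22 to 83.5 FPKM. RP11-3P17.3 went from 2.59 to 50.4 FPKM (3.84), and FAM72C from 1.83 to 22.2 FPKM (3.04). The sum over 4 FAM72 loci went only from 63.6 to 88.9 FPKM. Near-identical copies share reads, so the values of single members are uncertain.

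The cytokine genes IL8 and IL32 were among the largest falls. IL8 fell from 11.4 to 2.39 FPKM (-1.87), and its reads were 0.213 of the control (0.177 to 0.256). IL32 fell from 52.2 to 19.8 FPKM (-1.35). In SMG6/XRN1 and UPF1/XRN1, also labelled with XRN1, IL8 stood at 9.04 and 7.49 FPKM and IL32 at 40.9 and 30.7, all under 2-fold below the control. COPS8, a subunit of the COP9 signalosome, fell from 31.1 to 10.8 FPKM (-1.44), and the actin-binding adaptor DBNL from 33.9 to 13.3 FPKM (-1.28). The FPKM of KIF1B fell by 2.56 on the log2 scale while its estimated reads were 3145 and 2956. RNU6-11, AC025262.1 and U1 also fell, by 3.43, 1.68 and 1.24, but rested on at most 8 reads in either library.

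**Figure D1:**
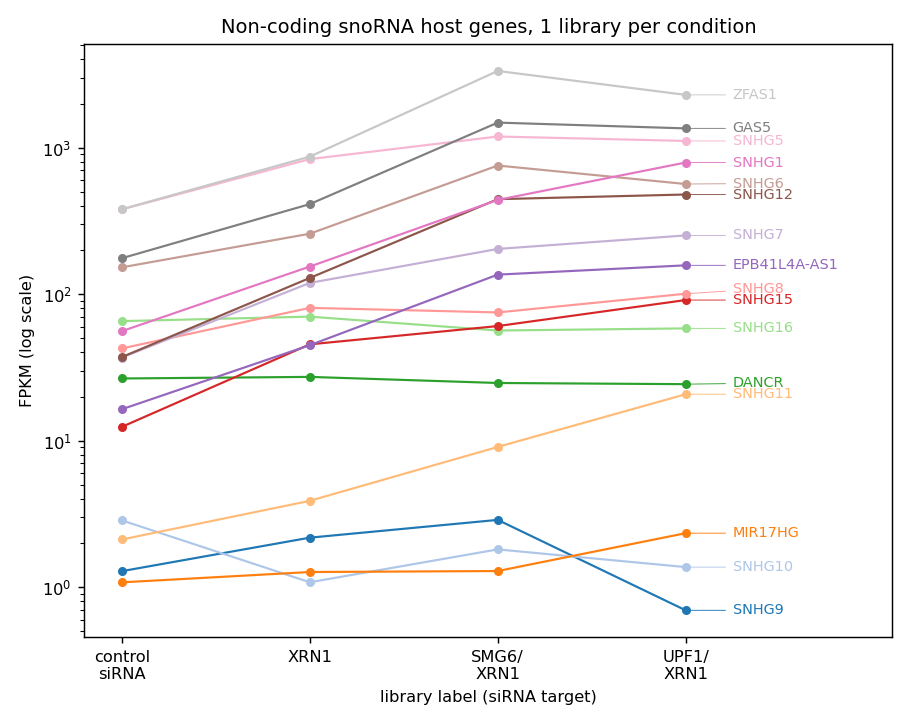
Each line is 1 of the 16 measured non-coding snoRNA host genes, with FPKM on a log axis and 1 point per RNA-seq library, named by its label; lines join the points of a gene and mark no time course. GAS5 stood at 176 FPKM in the control, 412 in XRN1, 1482 in SMG6/XRN1 and 1353 in UPF1/XRN1, while DANCR stayed between 24.3 and 27.3.

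The library labelled SMG6/XRN1 was compared with the library labelled XRN1 to see what changed when the endonuclease was targeted as well. Of 16 non-coding snoRNA hosts 7 rose, led by ZFAS1, GAS5 and SNHG12, and splicing regulators, p53 targets and known NMD targets were higher as groups. Ribosomal protein genes and histones were lower as groups. In all, 166 genes were at least 2-fold higher and 21 at least 2-fold lower, with a median log2 change of 0.12. Centring on that median gave 111 higher and 31 lower, which moved the share of calls that were higher from 88.8% to 78.2%. Directions rest on the label SMG6/XRN1, which neither target mRNA checked.

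Of the 16 non-coding snoRNA hosts, 7 rose, none fell, and the median was 0.64. ZFAS1 rose by 1.94, from 868 to 3336 FPKM, and its reads were 4.26 times those of XRN1 (4.17 to 4.35). GAS5 rose by 1.85, from 412 to 1482 FPKM. SNHG16 (-0.31) and DANCR (-0.13) did not pass 2-fold. Protein-coding snoRNA hosts had a median of -0.13, and TAF1D alone rose (1.83, from 136 to 486 FPKM), with NOP56 at -0.53 and RACK1 at -0.41. Among 25 known NMD targets the 2 that rose were GAS5 and ZFAS1, which are also non-coding snoRNA hosts, and the median was 0.32. Their members RPL12 (-0.34) and RPL3 (-0.18) lay below 0.

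Of 40 splicing regulators, SFPQ alone rose (1.40, from 278 to 735 FPKM), yet 34 lay above 0 and the median was 0.36. RBM39 (0.92) did not pass 2-fold, nor did any of the 21 measured p53 targets, of which 20 lay above 0, with FAS at 0.84 and BAX at 0.70 (list median 0.39). The 28 deadenylase and exosome genes had a median of 0.25 and no member past 2-fold. Among 5 nuclear-retained RNAs the median was 0.81. NEAT1, the scaffold of paraspeckles, rose by 1.24 from 4.20 to 11.3 FPKM, with PVT1 at 0.91, MALAT1 at 0.04 and OIP5-AS1 at -0.29.

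The 53 ribosomal protein genes had a median of -0.21 with 2 above 0 and none past 2-fold. The 11 replication-dependent histones had a median of -0.22. MT-ND6, which codes for a subunit of respiratory complex I, fell from 2385 to 1191 FPKM, and MT-CYB had -0.46 (median of the 2 measured mitochondrial mRNAs -0.73). A mitochondrial locus without a symbol, which holds MT-CO1, was listed at 0 FPKM in the control and in XRN1, at 2180 in SMG6/XRN1 and at 1317 in UPF1/XRN1. Its isoform signal rested on 1 transcript model, which overlaps its reference MT-ND5 without matching it. The value of the locus is therefore that of no single mRNA. How that locus was estimated bears on every mitochondrial value here. The locus RP5-857K21.4 fell from 13.7 to 2.33 FPKM (-2.14).

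Against random lists, the percentiles were 100 for non-coding snoRNA hosts, known NMD targets and splicing regulators, 99.91 for p53 targets, 99.98 for nuclear-retained RNAs and 98.2 for deadenylases and the exosome. They were 0 for ribosomal proteins, histones and the 2 measured mitochondrial mRNAs and 0.07 for protein-coding snoRNA hosts. The call for deadenylases and the exosome was lost under a filter on a mean of at least 5 FPKM. The remaining 8 lists were not apart. Immediate-early mRNAs reached 96.8 (median 0.24), and 98.5 with summed isoform signals, which put them apart above, with the transcription factor genes EGR1 (1.40) and FOSB (1.23) up and MYC down (-1.04, from 61.6 to 29.5 FPKM). The exon junction complex reached 92.1 (0.21), NMD factors 69.8 (0.18), interferon response genes 63.3 (0.14), decapping factors 46.7 (0.11), ATF4 targets 29.7 (0.07), housekeeping genes 25.4 (-0.00) and markers of other cell types 6.88 (-0.14). None of these last 7 lists had a member past 2-fold.

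Beyond the lists, the transcription factor gene ETV5 rose by 1.98, from 2.55 to 13.0 FPKM, and its reads were 3.75 times those of XRN1 (3.28 to 4.29). The histone H3.3 pseudogene H3F3AP4 rose by 2.28 to 324 FPKM but stood at 48.1 FPKM in UPF1/XRN1. RP11-313P13.3 rose by 1.95 and MECOM by 2.04, although the reads of MECOM were 1.46 times those of XRN1. The chromatin remodeller CHD8 rose by 5.26 to 459 FPKM, and KBTBD4 rose by 2.09, although their reads went only from 2161 to 2585 and from 395 to 457. RP11-329L6.1 rose by 6.02 in FPKM with 11 reads in XRN1 and 8 in SMG6/XRN1, and isoform signals summed per gene gave -0.38. Falls included RP11-3P17.3 (-4.00), FAM72C (-2.76), AC004448.5 (-2.84, from 229.5 to 31.2 FPKM) and the ribosomal protein pseudogene RPL9P9 (-1.20, from 22.9 to 9.35 FPKM). Their control values were 2.59 FPKM for RP11-3P17.3, 1.83 for FAM72C, 34.6 for AC004448.5 and 3.77 for RPL9P9, so these falls followed a high value in the library labelled XRN1. CAB39 fell by 2.03 on the log2 scale, whereas summed isoform signals gave 0.24. RNA5SP216 (-1.19) rested on 7 and 3 reads.

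The library labelled UPF1/XRN1 was compared with the library labelled XRN1 to see what changed when the NMD helicase was targeted as well. SNHG1, SNHG12, GAS5 and other non-coding snoRNA hosts rose, known NMD targets and p53 targets were higher as groups, and the ATF4 targets NUPR1 and ATF5 rose. Ribosomal protein genes and histones were lower as groups, and MT-ND6 and MYC fell. In all, 306 genes were at least 2-fold higher and 65 at least 2-fold lower, with a median log2 change of 0.02. Directions rest on the label UPF1/XRN1, under which UPF1 lay below the library labelled XRN1 but, by FPKM and by scaled reads, not below the control.

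Of the 16 non-coding snoRNA hosts, 8 rose, none fell, and the median was 1.03. SNHG1 rose by 2.35, from 154 to 792 FPKM, and its reads were 5.08 times those of XRN1 (4.92 to 5.25). SNHG11 rose by 2.15, from 3.89 to 20.8 FPKM. SNHG9 (-0.91) rested on 9 and 3 reads, and SNHG16 had -0.26. Of 25 known NMD targets, 6 rose, none fell, and the median was 0.59. GAS5 rose by 1.71 and TRA2B, a splicing regulator, by 1.58 from 105 to 317 FPKM, while RPL12 had -0.52 and RPL3 -0.42. NMD factors had a median of 0.32 with none past 2-fold, SMG9 at 0.66, SMG5 at 0.59 and UPF1 at -0.39. Of 54 protein-coding snoRNA hosts, TAF1D (1.67) and the transport receptor TNPO2 (1.12) rose, and the median was -0.32, with RPL4 at -0.62 and RPS2 at -0.59.

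Of 40 splicing regulators, 4 rose and none fell, with a median of 0.37. They were TRA2B, RBM39 (1.37, from 196 to 508 FPKM), SRSF10 (1.27) and LUC7L (1.19), while HNRNPC had -0.51 and HNRNPA1 -0.49. Of 24 ATF4 targets, 4 rose and none fell, with a median of 0.28. They were NUPR1 (1.30), ATF5 (1.26), SESN2 (1.09) and the amino acid transporter subunit SLC3A2 (1.08, from 62.2 to 133 FPKM). Of 21 p53 targets, SESN2 and the cell cycle inhibitor CDKN1A (1.04, from 17.1 to 36.2 FPKM) rose, none fell, and the median was 0.57. Among 5 nuclear-retained RNAs, NEAT1 (1.94) and PVT1 (1.09) rose, MALAT1 had 0.32 and OIP5-AS1 -0.59, and the median was 0.92.

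All 53 ribosomal protein genes lay below 0, with a median of -0.47, and 1 of them passed 2-fold. Over the control the same list had medians of 0.05 in SMG6/XRN1 and -0.21 in UPF1/XRN1, neither apart from random lists. The histone median was -0.42, with H2BC21 at -0.73. MT-ND6 fell by 1.58 on the log2 scale to 796 FPKM, and MT-CYB had -0.78 (median -1.18). The locus that holds MT-CO1, listed at 0 in XRN1, stood at 1317 FPKM here, and its estimate bears on these mitochondrial falls too.

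Against random lists, the percentiles were 100 for non-coding snoRNA hosts, known NMD targets, splicing regulators and p53 targets. They were 99.99 for nuclear-retained RNAs, 99.75 for ATF4 targets, 98.4 for NMD factors and 98.1 for deadenylases and the exosome (median 0.21). They were 0 for ribosomal proteins, histones and the 2 measured mitochondrial mRNAs and 0.11 for protein-coding snoRNA hosts. The call for deadenylases and the exosome was lost under a filter on a mean of at least 5 FPKM and with summed isoform signals. The remaining 6 lists were not apart. Immediate-early mRNAs stood at 89.8 (0.14), the exon junction complex at 79.2 (0.09), decapping factors at 75.4 (0.10), housekeeping genes at 55.8 (-0.07), interferon response genes at 27.6 (-0.04) and markers of other cell types at 5.76 (-0.36). ISG20 (2.08) and ISG15 (1.11) were the interferon response genes that rose, ISG20 with 30 and 53 reads.

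Beyond the lists, the septin pseudogene SEPT7P2 rose by 2.21, from 22.9 to 110 FPKM, and the chaperonin pseudogene CCT6P1 by 2.08, from 43.1 to 185 FPKM. The syntaxin gene STX1A rose by 2.25, from 2.69 to 16.5 FPKM, and its reads were 5.01 times those of XRN1 (4.03 to 6.27). RP11-33B1.1 rose by 2.23. RCOR1 (2.53) and CHD8 (2.23) rose in FPKM, RCOR1 with 1636 and 1850 reads. MYC fell by 1.46 on the log2 scale, from 61.6 to 21.8 FPKM. AMOT, which codes for angiomotin, fell from 25.2 to 7.11 FPKM (-1.69), its reads being 0.306 of XRN1 (0.292 to 0.321). The muscle gene MYOM2 fell by 1.52 on the log2 scale to 4.56 FPKM. AC004448.5 (-3.26), FAM72C (-2.73), RPL9P9 (-2.65) and RP5-857K21.4 (-2.35) also fell. Over the control, the first 3 of these had -0.57, 0.31 and -0.33, whereas RP5-857K21.4 ended at 1.89 FPKM against 14.6 in the control. CAB39 fell by 2.19 on the log2 scale, whereas summed isoform signals gave 0.08.

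**Figure D2:**
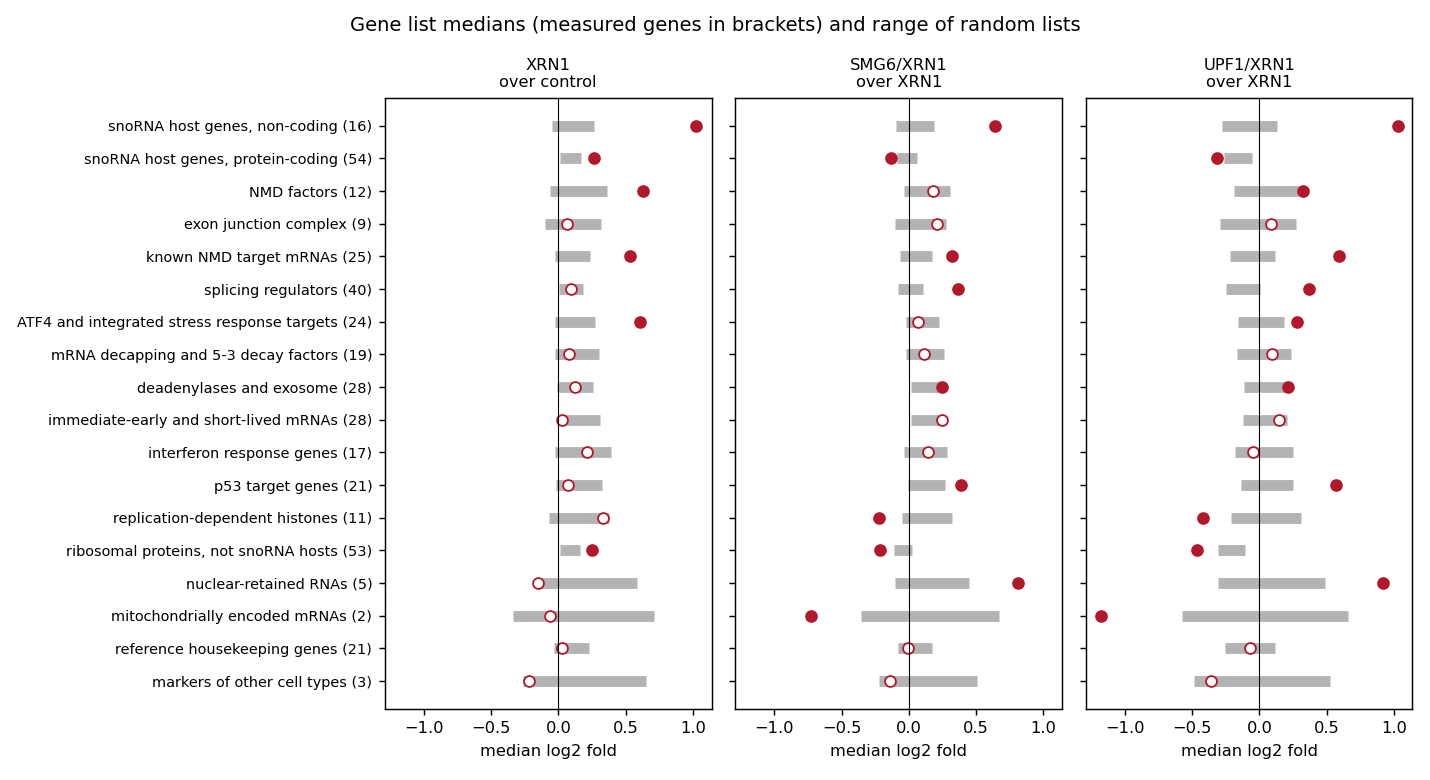
Median log2 change of each of the 18 gene lists in the 3 main comparisons of libraries named by label, with the central 95% of 10000 expression-matched random lists as a grey bar. Filled points are lists whose median lay outside that range, such as non-coding snoRNA hosts (1.02, 0.64 and 1.03) and ribosomal proteins (0.25, -0.21 and -0.47).

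The comparisons with SMG6/XRN1 and with UPF1/XRN1 were set side by side to see which genes moved in both. Rises were shared by 109 genes, falls by 10, and 0 genes went opposite ways, although the XRN1 library common to both comparisons pushes signs to agree. SNHG12 rose by 1.78 and 1.88, from 129 to 445 and 479 FPKM. GAS5 rose by 1.85 and 1.71, TAF1D by 1.83 and 1.67, EPB41L4A-AS1 by 1.58 and 1.79, and SEPT7P2 by 1.62 and 2.21. The medians of the 5 nuclear-retained RNAs, which could rise with nuclear RNA in a cytoplasmic extract, were 0.81 and 0.92 in the same comparisons. MALAT1 did not pass 2-fold and OIP5-AS1 lay below 0 in both. Over the control the list was not apart (percentiles 61.1 and 79.9), and nuclear RNA in the extract was not tested. In all, 7 of the 16 non-coding snoRNA hosts rose in both, as did 1 of 54 protein-coding hosts and 2 of 25 known NMD targets.

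Others with large rises in both were CHD8, whose reads did not follow, TBC1D3C (1.73 and 1.75), CLHC1 (1.72 and 1.81), AHSA2 (1.58 and 1.77), RP11-15J10.1 (1.55 and 1.86), CUZD1 (1.54 and 1.88) and ARHGAP11B (1.52 and 1.79). The primate-specific TBC1D3 family, summed over 6 loci, stood at 34.4 FPKM in XRN1, 75.5 in SMG6/XRN1 and 83.5 in UPF1/XRN1. EPB41L4A-AS1 and ZFAS1 lie antisense to other genes, and the counting strand was not given in the sources used here, so reads of those genes cannot be told apart from theirs.

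Both comparisons used the same XRN1 library. Independent lists of these sizes would share 4.18 rises and 0.112 falls, and 100 simulated pairs of unchanged libraries against 1 baseline shared 2.22 rises on average and at most 6. Across genes, which are not replicates, Pearson r was 0.776, Spearman rho 0.774 and the covariance 0.125, against 0.50 and 0.0558 for simulated r and covariance. With no library in common, SMG6/XRN1 over XRN1 and UPF1/XRN1 over control shared 116 rises against 17 for independent lists and 4 falls, with r 0.502, and 7 genes went opposite ways. The reverse pairing shared 204 rises against 28.5 and 3 falls, with r 0.504, and 8 genes went opposite ways. With 1 baseline library, part of the excess over independent lists and over the simulation may come from the shared library. The simulated noise was normal, so values far off in the XRN1 library alone were not drawn.

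Set against the control directly, 1131 genes were higher and 32 lower in the library labelled SMG6/XRN1, and 1244 higher and 70 lower in UPF1/XRN1. Centring on the median gene, at 0.25 and 0.15, gave 635 higher and 79 lower, and 942 higher and 148 lower. Non-coding snoRNA hosts had medians of 1.94 and 2.24, with 10 and 11 of 16 higher. Known NMD targets had medians of 0.94 and 1.31, with 10 and 17 of 25 higher. NMD factors had medians of 0.91 and 0.94, with 4 and 5 of 12 higher. Splicing regulators had 0.40 and 0.57 and ATF4 targets 0.63 and 0.77, and these 5 lists lay above the random range in both. The 2 measured mitochondrial mRNAs of 13 listed (-0.79 and -1.24) and the 3 markers of other cell types (-0.36 and -0.58) lay below it in both.

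Several lists apart over the library labelled XRN1 were not apart over the control. They were the histones (0.05 and -0.01, percentiles 5.54 and 17.6), the nuclear-retained RNAs (0.36 and 0.47, 61.1 and 79.9), the protein-coding snoRNA hosts (0.10 and -0.08, 90.2 and 71.6) and the deadenylases and exosome (0.35 and 0.28, 91.5 and 91.4). The ribosomal proteins stood at percentiles 77.5 and 6.46. The p53 targets were not apart in SMG6/XRN1 (0.44, 92.9) but were in UPF1/XRN1 (0.61, 99.7).

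Isoforms were compared because the design text assigns the RNA-seq to NMD isoforms. Isoforms whose reference transcript is annotated as an NMD substrate were higher in each of the 3 libraries labelled with a depletion, more often than isoforms annotated as protein coding. Of 3583 NMD isoforms, 33.8% (95% interval 32.2 to 35.3) were at least 2-fold higher in XRN1 than in the control. The share was 40.0% (38.4 to 41.6) for SMG6/XRN1 over XRN1 and 44.7% (43.1 to 46.4) for UPF1/XRN1 over XRN1. Of 25734 protein-coding isoforms, 17.3%, 17.2% and 17.7% were higher. Over the control, 56.2% and 59.1% of NMD isoforms were higher in SMG6/XRN1 and UPF1/XRN1, against 24.5% and 23.9% of protein-coding ones.

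The median log2 changes of NMD isoforms were 0.45, 0.69 and 0.79 in the 3 main comparisons, each at percentile 100 of expression-matched random lists, whose medians were 0.20, 0.32 and 0.28. Protein-coding isoforms had 0.12, 0.19 and 0.06, each at percentile 0. Processed transcripts had 0.36, 0.46 and 0.44, each at 100. Retained-intron isoforms had 0.29 (percentile 100), 0.37 (87.7) and 0.42 (99.99). The 625 lincRNA isoforms had 0.21 (76.2), 0.46 (98.3) and 0.41 (90.1), and the 1165 antisense isoforms 0.08 (0.48), 0.33 (15.8) and 0.20 (0.06). NMD isoforms took 2.51% of all signal in the control, 2.86% in XRN1, 3.59% in SMG6/XRN1 and 3.98% in UPF1/XRN1, while protein-coding isoforms went from 70.3% in the control to 65.0% in UPF1/XRN1. In the authors' deposited table, 49.5% of these NMD isoforms carry the authors' own NMD mark, against 17.6% of protein-coding ones. That mark was found to mean a value above 0 in both SMG6/XRN1 and UPF1/XRN1 and over 2 times the control in both.

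**Figure D3:**
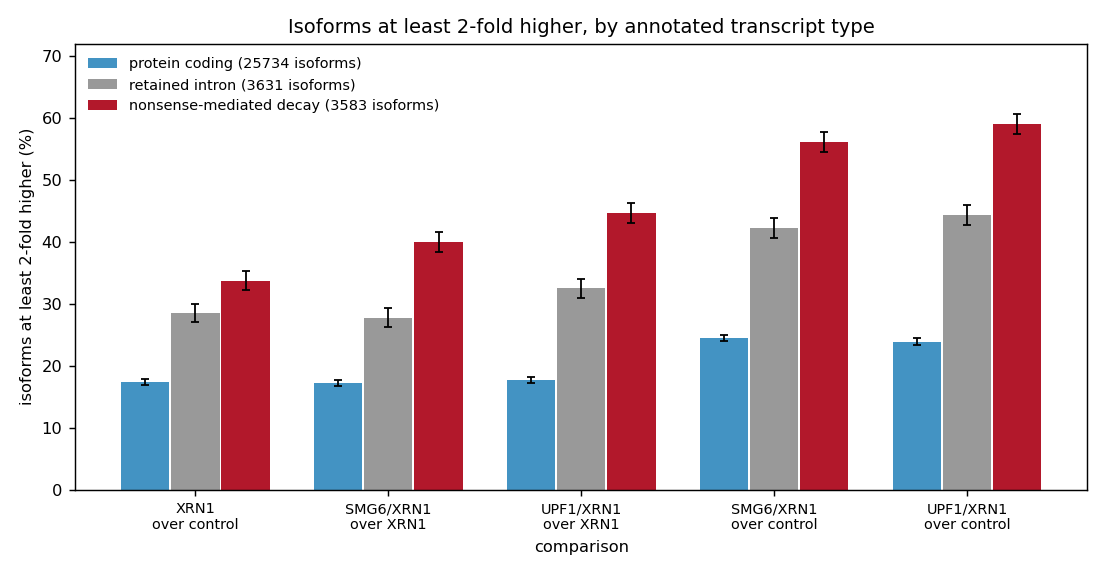
Percent of isoforms at least 2-fold higher for each annotated transcript type in 5 comparisons of libraries named by label, with exact binomial 95% intervals as bars. NMD isoforms reached 33.8%, 40.0% and 44.7% in the 3 main comparisons, against 17.3%, 17.2% and 17.7% of protein-coding isoforms.

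Over all 61408 isoforms compared, 14923 were higher and 7737 lower in XRN1 than in the control. SMG6/XRN1 over XRN1 gave 15430 higher and 5710 lower, and centring on the median moved these to 12038 and 7431, or from 73.0% to 61.8% higher. UPF1/XRN1 over XRN1 gave 16613 higher and 7078 lower. In a simulation of SMG6/XRN1 over XRN1 with counting error only, 4.21% of unchanged isoforms passed 2-fold. Errors in sharing reads among isoforms were not simulated, so this is no rate of false calls in these data. Isoforms that shared some but not all junctions with a reference transcript were higher in 30.6%, 32.4% and 35.4% of 18340 cases, against 21.6%, 22.0% and 23.6% of 41684 exact matches. They were also lower more often, in 15.8%, 12% and 13.2% against 11.2%, 8.29% and 10.9%, and their medians were 0.20, 0.42 and 0.45 against 0.18, 0.26 and 0.17. Many isoforms rose while the other isoforms of the gene together moved by under 1.5-fold, namely 9249 of 13914 in the first comparison, 11581 of 14574 in the second and 11580 of 15693 in the third. The same share over all isoforms was not computed. Quartiles of the gene log2 changes, -0.06 and 0.39, -0.06 and 0.30, and -0.22 and 0.29, also lie within 1.5-fold. These counts therefore do not show that isoforms which rose differ from others in this respect.

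The largest isoform rises were set by a near-0 estimate in the library labelled XRN1. An isoform of the splicing regulator PTBP2 was at least 398-fold higher in SMG6/XRN1 and at least 299-fold higher in UPF1/XRN1 than the floor of 3 reads, yet it held 714 estimated reads in the control. Isoforms of EPB41L3, ZDBF2, SETD1A and GOLGB1 were at least 248, 239, 216 and 256-fold higher in SMG6/XRN1. Isoforms of AHCYL1, GNGT1 and ASCC2 were at least 310, 223 and 190-fold higher in UPF1/XRN1. The reference transcripts of these isoforms were annotated as protein coding.

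Splicing regulators were then examined for the share of each gene's reads that lay in its NMD isoforms, a comparison chosen after the values were seen. The median over 28 genes was 8.70% in the control, 12.2% in XRN1, 20.9% in SMG6/XRN1 and 22.6% in UPF1/XRN1. HNRNPL went from 7.50% in the control to 14.9%, 52.0% and 66.9%, and TRA2B from 12.4% to 28.1%, 52.4% and 64.6%. SRSF3 went from 9.90% to 33.6%, 46.5% and 54.9%, SRSF7 from 16.1% to 31.3%, 47.3% and 55.1%, and SRSF2 from 1.24% to 9.15%, 23.0% and 22.5%. HNRNPA1 stood at 42.0%, 41.7%, 42.3% and 42.2%. The share was above the control with separate exact intervals in 23 of 28 genes for SMG6/XRN1 and 24 for UPF1/XRN1, and below it in 0 and 1 (HNRNPC). Over the same libraries, 18 ribosomal protein genes had medians of 0.860%, 0.792%, 0.788% and 0.840%, and 9 housekeeping genes 0.251%, 1.11%, 0.936% and 1.41%. Behind these medians, 6 of the 18 ribosomal protein genes were above the control with separate intervals in each co-depletion and 2 below. RPLP0 went from 2.96% in the control to 14.0% in UPF1/XRN1, and RPS9 from 2.96% to 13.0%. Of the housekeeping genes, 3 were above and 3 below in SMG6/XRN1, and 5 above and 2 below in UPF1/XRN1. Despite the low medians, single genes of these groups held large shares in the control, with B2M at 69.7%, RPS15A at 54.7% and ACTB at 37.5%. ACTB went down to 26.5% in UPF1/XRN1, and RPS15A stood at 56.5% there. A large share of reads assigned to NMD isoforms, as in HNRNPA1, therefore need not measure an NMD substrate. The reads are estimated assignments to overlapping isoforms, and the intervals cover counting error only.

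**Figure D4:**
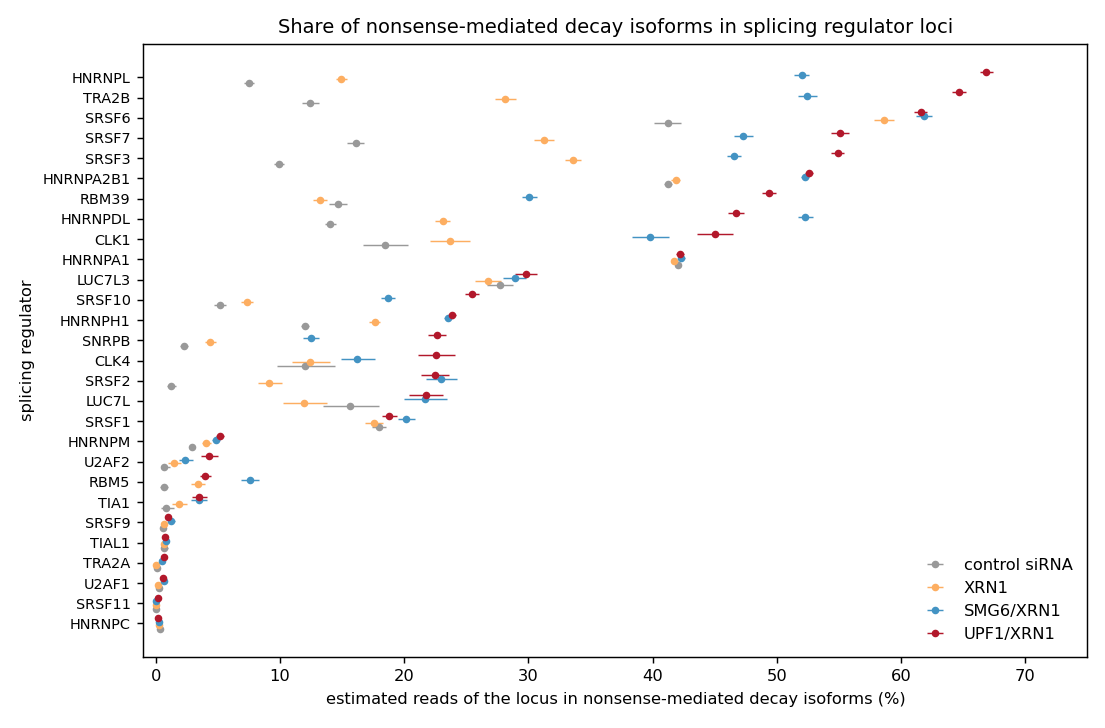
Percent of each gene's estimated reads in isoforms annotated as NMD substrates, for 28 splicing regulators in the 4 RNA-seq libraries named by label, with exact binomial 95% intervals. HNRNPL went from 7.50% in the control to 66.9% in UPF1/XRN1, while HNRNPA1 stayed near 42.0%.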

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

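The tests on exchanged labels, cleavage fragments, masking by NMD factors, library-wide scale and left-out loci were chosen only after the result was seen.

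A signal that no measured list member or named gene covers was found at a mitochondrial locus, which has no symbol and holds MT-CO1. It was listed at 0 FPKM in the control and in the library labelled XRN1, at 2180 in SMG6/XRN1 and at 1317 in UPF1/XRN1. In these last libraries it held 2.01% and 1.33% of all estimated reads. The locus passed the filter, so it is counted among the genes higher in both co-depletions. It is among 25 compared loci listed at 0 in some library. In the authors' deposited table, 372 of 1252 isoforms outside every reference locus (29.7%, over 358 loci) carried the authors' NMD mark. Together these 372 isoforms held 3035 reads in the control, 8698 in XRN1, 12327 in SMG6/XRN1 and 14777 in UPF1/XRN1, while the mark itself requires a rise over the control.

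By FPKM, the targeted mRNAs XRN1, SMG6 and UPF1 lay below the control in 2 of 5 targeted values, a count that depends on the scale. An exchange of labels among the 4 RNA-seq libraries that would put every target below the control is argued against. Of 24 assignments, 0 did so with the known NMD targets not lower. This rests on the NMD targets, because 4 of the 24 put every target mRNA below the control. All 4 take SMG6/XRN1 as the control, in which the NMD targets had a median 0.94 above the library labelled control. The labels as given fail this rule as well. An exchange among libraries whose depletion does not show in the mRNA was therefore not tested and stays open. A single library from outside the set also stays open. A rise of NMD factor mRNAs that masks the fall of SMG6 and UPF1 goes with the median of the 10 other factors over the control. That median was 0.91 in SMG6/XRN1 (percentile 99.99) and 0.98 in UPF1/XRN1 (99.94), but masking leaves XRN1 aside. Over the library labelled XRN1, the 12 NMD factors had a median of 0.18 in SMG6/XRN1, at percentile 69.8, inside the random range. SMG6 reads there were 0.982 times those of XRN1, so masking of SMG6 was not seen over that baseline. RISC cleavage fragments kept by the loss of XRN1 could not be tested, since 0 tables give read positions along the mRNA. A depletion too weak to show in the mRNA also stays open and was not tested.

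In some genes FPKM moved without the reads, such as CHD8, KIF1B and CAB39. Discordant loci numbered 66 in XRN1 over control, 22 in SMG6/XRN1 over XRN1 and 39 in UPF1/XRN1 over XRN1, with a median absolute log2 change of reads of 0.170 over all 127. Reads reassigned to a shorter isoform of the locus would move reads divided by transcript length the way the FPKM moved, and 43.9% (31.7 to 56.7) of 66 loci did so. The test was void, because only 52.0% of the discordant loci had lengths, so this possible explanation stays open. No biological explanation was tested.

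Genes at least 2-fold higher outnumbered those lower in all 5 comparisons. A library-wide scale as the whole cause is argued against for XRN1 over control, where 362 genes higher and 65 lower remained after centring, a ratio of 5.57. Loci left out of the gene table were checked where their mean signal was at least 334 units. That is worth 1 FPKM at the median ratio of signal to FPKM. Only 61 left-out loci reached it, and 0 of these were at least 2-fold lower in XRN1 than in the control. In the other comparisons, all 61 counted as lower would still leave more genes higher, SMG6/XRN1 over XRN1 being nearest with 166 higher and 21 lower. Left-out loci of that signal are therefore argued against as the cause. Locus lengths were not used, and short loci reach 1 FPKM on less signal, so left-out loci of lower signal stay open. The depletions that the labels name stay open, as an untested explanation.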

How the results depend on the processing

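The settings with a pseudocount of 50 or one worth 1 FPKM, and the upper quartile as filter, were chosen only after the data were seen; all others were planned. Of 679 values under alternatives, 73 counts, shares and correlations stayed alike and 63 moved, 258 list medians kept their call (54 of them under centring, which cannot move a percentile), and 251 named-gene values kept their sign and stayed past 2-fold. The cause of the moves below was not tested, except that stricter filters compare fewer genes and a lower pseudocount lets low genes pass. With 1 library per condition no library was left out in turn.

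For genes, values are given for XRN1 over control, SMG6/XRN1 over XRN1 and UPF1/XRN1 over XRN1 in turn. With a pseudocount of 0.1, 973, 356 and 529 were higher and 107, 40 and 215 lower, 1730 were higher in SMG6/XRN1 over control, and 241 were higher in both co-depletions. With a mean of at least 5, 315, 102 and 203 were higher and 25, 11 and 41 lower, and 730 and 819 were higher in SMG6/XRN1 and UPF1/XRN1 over control. With isoform signals summed per gene, 996, 424 and 573 were higher and 103, 32 and 157 lower, 2072 and 2003 were higher over control, 301 were higher in both, and 1 of 5 targeted values lay below the control. Of the genes called in the FPKM table, these summed signals also called 453, 144 and 263 higher and 40, 16 and 56 lower. They used a pseudocount of 1 signal unit, which lets low genes pass. With a pseudocount worth 1 FPKM on the sums, 454, 107 and 222 were higher and 17, 5 and 38 lower. Calls shared with the FPKM table cannot exceed these counts under that setting. Centring left 635 higher in SMG6/XRN1 over control. Without a shared library, r was 0.502 and 0.504 and the second pairing shared 204 rises.

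RP11-329L6.1 reversed in SMG6/XRN1 over XRN1, to -0.38 with summed signals and -0.0408 with the pseudocount worth 1 FPKM. CAB39 reversed to 0.244 and 0.239 in SMG6/XRN1 and to 0.0770 and 0.0753 in UPF1/XRN1 under these settings. A further 19 named-gene values fell under 2-fold with the same sign. Among list medians, 4 calls were lost, all for deadenylases and the exosome, and 5 gained. The exon junction complex moved apart below in XRN1 over control (-0.08 with both sums, percentiles 2.37 and 2.38), nuclear-retained RNAs did so there with the pseudocount worth 1 FPKM (2.47), and immediate-early mRNAs moved apart above in SMG6/XRN1 over XRN1 (98.5 and 99.0).

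For isoforms in the same order, no filter gave 29711, 34428 and 38404 higher and 22160, 17696 and 18678 lower. A mean of at least 5 gave 23558, 26302 and 28512 higher and 15370, 11884 and 13062 lower, and 14233, 18843 and 18972 risen without their gene. The upper quartile gave 5545, 4874 and 5300 higher and 1746, 1303 and 2183 lower, and a pseudocount of 50 gave 9791 higher and 4605 lower in XRN1 over control. Isoforms sharing part of a reference structure were higher more often than exact matches by 8.98, 10.4 and 11.8 points, by 5.82, 6.57 and 7.66 points with a mean of at least 5, and by 7.14, 8.33 and 9.41 points with a pseudocount of 50. The median of the NMD isoforms stayed at percentile 100 under every alternative run for it.

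Depth limits low genes: 8 reads or fewer lay behind RNU6-11, AC025262.1 and U1, and near-0 isoform estimates set the largest isoform folds.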

Other observations

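The tests of transcript structure were written before their results were seen for UPF1/XRN1 over XRN1 only. Their values in the other comparisons had no outcome written beforehand, and the choice of genes in the next paragraph was made only after the results were seen.

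More splicing factor genes than those described had a larger share of their reads in NMD isoforms in the co-depletions, which says nothing of where those reads came from. HNRNPDL went from 14.1% of its reads in the control to 23.1% in the library labelled XRN1, 52.3% in SMG6/XRN1 and 46.7% in UPF1/XRN1. RBM39 went from 14.6% to 13.2%, 30.1% and 49.4%, and SRSF10 from 5.19% to 7.35%, 18.7% and 25.5%. SNRPB went from 2.31% in the control to 12.5% in SMG6/XRN1 and 22.7% in UPF1/XRN1. LUC7L3 had 27.7%, 26.8%, 28.9% and 29.8%. Over 23 protein-coding snoRNA hosts the median was 0.863% in the control, 0.554% in XRN1, 2.14% in SMG6/XRN1 and 2.61% in UPF1/XRN1. The share was above the control with separate intervals in 11 and 13 of them and below it in 2 in each co-depletion, with EEF1B2 going from 11.1% to 2.84% and 1.22%.

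Features known to attract NMD were looked for in 22844 isoforms annotated as protein coding. The hypothesis that an exon junction over 50 nt downstream of the stop codon goes with a rise was tested on 138 such isoforms. Their median log2 change in UPF1/XRN1 over XRN1 was 0.27, against 0.05 for the rest, at percentile 97.9 of expression-matched lists, which is consistent with the hypothesis by a narrow margin. The same isoforms stood at 95.8 in SMG6/XRN1 over XRN1 (0.33) and at 72.8 in XRN1 over control (0.19), inside the range of random lists. Over the control, UPF1/XRN1 was also inside it, at 97.2 (0.46), and SMG6/XRN1 outside it, at 99.86 (0.69), so the call for UPF1/XRN1 depends on the baseline.

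The hypothesis that a long 3' untranslated region goes with a rise was argued against. The 5677 isoforms with the longest such regions, at least 1738 nt, and no such junction had a median of -0.01 in UPF1/XRN1 over XRN1, against 0.08 for the rest, at percentile 0. They stood at percentile 0 in XRN1 over control as well (0.09 against 0.14) and at 0.055 in SMG6/XRN1 over XRN1 (0.15 against 0.19). Over the control, SMG6/XRN1 and UPF1/XRN1 were also at 0, so the lower median was not particular to UPF1/XRN1. An ATG upstream of the coding start, in 11963 isoforms, went with 0.08 against 0.01 in UPF1/XRN1 over XRN1, at percentile 100. These isoforms stood at 100 in SMG6/XRN1 over XRN1, but at 2.40 in XRN1 over control (0.12 against 0.13). This may point to upstream open reading frames, although the differences are small, isoform reads are estimated, and transcript length and library coverage were not separated from these features.

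The locus of GAPDH, outside the gene table, held 57657 estimated reads in the control, 59243 in XRN1, 47835 in SMG6/XRN1 and 43344 in UPF1/XRN1.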
